A study of Mus musculus with 2 samples.

How the data were processed

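Colorectal tumours induced in mice with azoxymethane, a carcinogen, and dextran sulfate sodium, which causes colitis, were profiled by droplet single-cell RNA sequencing with 10x Genomics chemistry. Per the labels' protocols, the tumours of each genotype were pooled before dissociation with trypsin, so that 1 library stands for each of the 2 genotypes. WT is the library of mice with floxed Mtch2 alleles and no Cre, and cKO is the library of mice that also carry Cre recombinase under the Villin promoter, which is active in the intestinal epithelium. The genotype of each library was taken from its labels.

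The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized, made with Cell Ranger 7.2.0 per the file headers. The submitters' processing notes also name Seurat 3.0 and the genome build mm10. Filters that the authors applied to cells after counting are not given in the sources used here. The matrices held 32285 genes, of which 32158 were matched by identifier to the GENCODE annotation release 21 of GRCm38, from which the gene coordinates were taken. The WT matrix held 9445 barcodes with 116066712 UMIs, and the cKO matrix 6723 barcodes with 97364087 UMIs. No barcode had fewer than 500 UMIs.

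Barcodes with fewer than 500 detected genes (905 WT, 1607 cKO) or more than 25% mitochondrial UMIs (671 WT, 487 cKO) were left out. Scrublet scores from scanpy 1.11.5 were computed per library, and the barcodes with the highest scores were marked as doublets, at 0.8% of barcodes per 1000 barcodes (714 WT, 362 cKO, of which 660 and 274 remained to be removed after the other filters). This left 7243 WT and 4388 cKO cells, with medians of 3724 and 6928 UMIs. The kept cells of both libraries were clustered together without integration, on 2000 variable genes without Mtch2 and without sex-linked and immune receptor genes, 30 principal components and 20 neighbours, with Leiden resolution 1 (leidenalg 0.10.2), which gave 32 clusters. Clusters were called after marker lists of 15 cell classes fixed before the data were examined. The scoring rule that turns markers into a name was set after the clusters were seen. A cluster took the name of a class whose markers averaged at least 2 on the log2 scale above the mean of all clusters, and was called epithelial-like where no other class reached 1 and its level of 10 pan-epithelial genes lay above the midpoint of the clusters. It left clusters unnamed that carried markers of several classes, or whose leading genes went against the name. Unnamed clusters held 41.7% of WT and 16.8% of cKO cells, and the largest, cluster 1, held 35.8% and 13.0% with medians of 739 and 753 UMIs.

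Because there is 1 library per genotype, no test between genotypes was possible and none was made. UMIs were summed per library and class and scaled to 1000000 UMIs (CPM). Ratios are log2 of cKO over WT after adding 0.5 counts. Intervals are 95%. They are exact for levels (Poisson), for ratios of single genes (conditional binomial) and for shares (Clopper-Pearson). For list medians they are not exact, but the middle 95% of the medians over 1000 Poisson draws of the members' counts. Differences of shares combine the 2 exact intervals by the square-and-add rule. All intervals cover counting error only, not variation between mice or tumours. Classes with at least 100 cells in each library were compared: epithelial-like, T-like, macrophage and monocyte-like, and neutrophil-like.

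Of 35 gene lists fixed before the data were examined, 32 were computed. The 2 fibroblast lists and the endothelial list were not evaluated, since those classes held fewer than 100 cells in a library. A member was measured at 10 CPM or more in either library. The median ratio of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and is given as a percentile that describes these libraries. The random lists draw genes independently, so the percentile does not account for genes that vary together. The rule for named genes was also fixed before the data were examined. It took, per class, genes with at least 50 CPM in a library, an interval of the ratio that excluded no difference, the same direction in every cluster of the class with at least 100 cells in each library, and at least 20% of the highest class level, as a guard against free RNA. The highest level was taken over named classes, so unnamed clusters did not enter this guard. Free RNA passing between clusters of the same class was not covered by it. The 15 largest ratios each way were named in epithelial-like cells and the 5 largest each way in the other classes. Mitochondrially encoded, ribosomal, immunoglobulin, T cell receptor, haemoglobin and sex-linked genes and unnamed gene models were left out.

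The share of cycling cells was planned as the share with at least 2 UMIs of the G2 and M phase list after thinning each cell to 3000 UMIs. Single random draws of the thinning differed among themselves, so the share was computed as the exact mean over draws, a choice made after seeing the data. A call at 10 UMIs was also added after seeing the data. The ratio and interval code was tested on simulated counts with 200 changed genes per class. All 1.25-fold changes were recovered in the right direction among the 3957 epithelial-like genes, 72% among 3722 in T-like cells, 86% among 3409 in macrophage and monocyte-like cells and 56% among 2557 in neutrophil-like cells, where 86% of 1.5-fold changes were recovered. Of 40 simulated lists of unchanged genes per class, 4 in epithelial-like, 1 in T-like, 3 in macrophage and monocyte-like and 0 in neutrophil-like cells lay below percentile 2.5 or above 97.5. Their percentiles ran from 0.12 to 98.33 in epithelial-like and from 0.20 to 99.2 in macrophage and monocyte-like cells, so a percentile within these bounds alone does not set a list apart. The simulated genes varied independently, so the simulation cannot show that a percentile beyond these bounds does. Alternatives covered the barcode, mitochondrial and doublet filters, the clustering resolution, the scaling, the weighting of cells and clusters, the minimum level, the pseudocount and the cycling call. Cells were also assigned a sex of origin from Xist and Y-linked genes, which was added after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.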

Results

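Tumours of the colon and rectum from mice with floxed Mtch2 alleles (WT) and from mice in which Cre under the Villin promoter recombines those alleles in the intestinal epithelium (cKO) were compared at single-cell level, with 1 pooled library per genotype. Mtch2 encodes mitochondrial carrier homolog 2, a protein of the outer mitochondrial membrane. The series is about MTCH2 loss, the transcription factor E2F4, the transferrin receptor gene Tfrc and ferroptosis, an iron-dependent form of cell death. After filtering, 7243 WT and 4388 cKO cells remained, of which 2924 and 1867 were epithelial-like, with 85900896 and 63231916 UMIs. The largest epithelial-like cluster was cluster 2 in WT (21.5% of the class) and cluster 3 in cKO (16.5%). There were no replicates, so each difference below is a difference between 2 libraries, and its interval covers counting error only.

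Mtch2 was lower in the epithelial-like cells of the cKO library and about equal in T-like and macrophage-like cells, which do not express Villin. In epithelial-like cells Mtch2 stood at 92.1 CPM (95% interval 90.1 to 94.2) in WT and 23.8 CPM (22.6 to 25.1) in cKO, a log2 ratio of -1.95 (-2.03 to -1.87). It was lower in each of the 9 epithelial-like clusters, with 14.8 to 28.1 CPM left in cKO. In T-like cells Mtch2 was at 48.3 CPM in WT and 41.4 CPM in cKO, and in macrophage and monocyte-like cells at 53.5 and 51.3 CPM, and both intervals of the ratio included 0. Among the T-like clusters Mtch2 was lower in cluster 12, at 60.3 and 42.9 CPM, a log2 ratio of -0.49 (-0.97 to -0.0029). It stood at 40.1 and 41.9 CPM in cluster 15 and at 34.0 and 33.6 CPM in cluster 23. In neutrophil-like cells Mtch2 was at 44.7 CPM (32.1 to 60.6) in WT and 19.4 CPM (13.7 to 26.8) in cKO, from 41 and 37 UMIs, and Tfrc differed alike, at 53.4 and 24.7 CPM. In classes of fewer than 100 cells per library, Mtch2 was also lower in dendritic-like cells, at 69.4 and 36.5 CPM, a log2 ratio of -0.92 (-1.50 to -0.36), and in plasma-like cells, at 49.2 and 20.2 CPM, -1.24 (-2.47 to -0.23), from 65 and 47 UMIs and from 33 and 10. The gene (ENSMUSG00000027282) lies on chromosome 2, 90847155 to 90866810, plus strand, in GRCm38. Counts come from the 3' end of transcripts, and which exons are floxed is not given in the sources used here, so transcripts that lost an exon can still be counted.

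**Figure D1:**
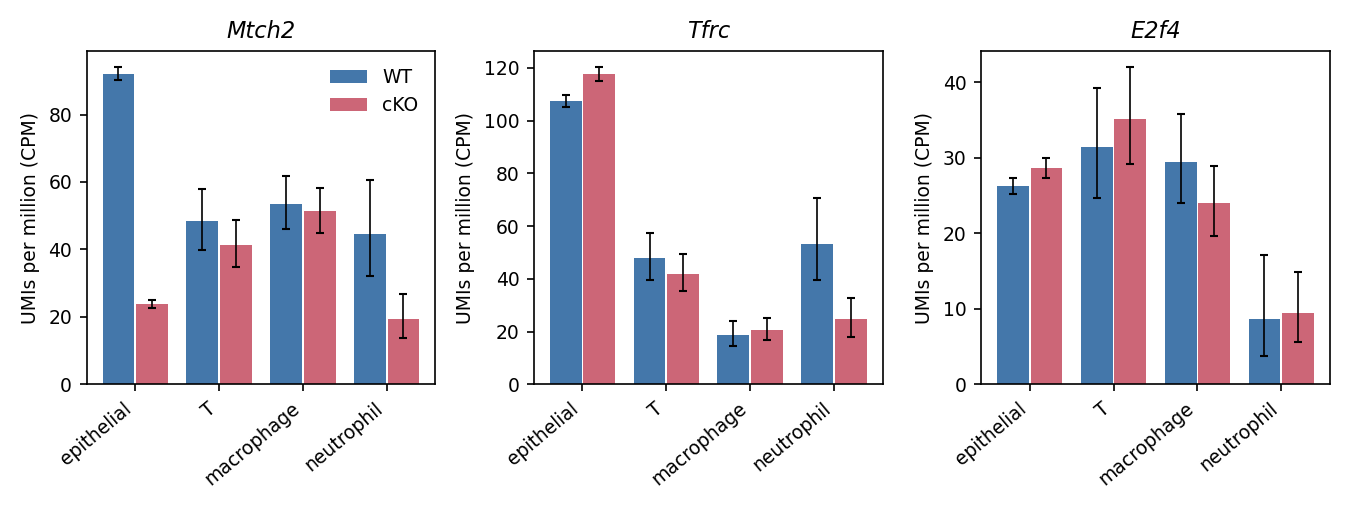
Levels of Mtch2, Tfrc and E2f4 in CPM (UMIs of the gene scaled to 1000000 UMIs of the class, vertical axes) in 4 cell classes, with bars for the WT and cKO libraries and exact 95% Poisson intervals that cover counting error only. Mtch2 stands at 92.1 CPM in WT and 23.8 CPM in cKO epithelial-like cells, while Tfrc stands at 107 and 118 CPM.

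Tfrc and E2f4 were slightly higher in cKO epithelial-like cells. Tfrc, which imports transferrin-bound iron (ENSMUSG00000022797, chromosome 16, 32608920 to 32632794, plus strand), stood at 107 CPM (105 to 110) in WT and 118 CPM (115 to 120) in cKO, a log2 ratio of 0.13 (0.088 to 0.18). E2f4, a member of the E2F family that acts with pocket proteins (ENSMUSG00000014859, chromosome 8, 105297663 to 105305370, plus strand), stood at 26.3 CPM (25.2 to 27.4) and 28.7 CPM (27.4 to 30.02), a log2 ratio of 0.13 (0.037 to 0.22). The size of both differences depended on how cells were weighted. With each epithelial-like cell weighted equally the log2 ratio was 0.0016 for Tfrc and -0.058 for E2f4. With equal weights of the clusters the log2 ratio of Tfrc was 0.013. Here and below this setting means the clusters of a class with at least 100 cells in each library, and so leaves out cluster 14. In cells assigned female the log2 ratio was 0.48 for Tfrc and 0.30 for E2f4. Within clusters Tfrc went both ways, from -0.27 (-0.76 to 0.20) in cluster 7 and -0.21 (-0.35 to -0.080) in cluster 3 to 0.36 (0.17 to 0.56) in cluster 14. It stood at -0.13 (-0.27 to -0.0034) in cluster 2 and at 0.19 (0.071 to 0.32) in cluster 16. In clusters 4, 5, 8 and 9 it was higher with intervals that included 0. In the unnamed cluster 13, which scored as epithelial-like, Tfrc stood at -0.38 (-0.54 to -0.23).

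Genes of ferroptosis and iron handling differed little between the libraries in epithelial-like cells. No measured member of the 3 lists differed by 1.5-fold. Of 25 measured ferroptosis drivers, 9 were higher and 16 lower in cKO, with a median log2 ratio of -0.079 (-0.095 to -0.036), at percentile 3.90 of the matched random lists. This median was -0.01 with all deposited barcodes and -0.033 both with equal weights of the clusters and with the unnamed cluster 13 added. The lowest driver was Alox12, a lipoxygenase, at 62.5 CPM in WT and 45.4 CPM in cKO. Of 26 suppressors, 12 were higher and 14 lower, with a median of -0.027 (-0.054 to 0.019) at percentile 50.8. The cystine transporter gene Slc7a11 stood at 25.6 and 36.0 CPM, a log2 ratio of 0.50 (0.41 to 0.58), and Slc40a1, which encodes the iron exporter ferroportin, at 26.5 and 36.2 CPM, 0.45 (0.37 to 0.54). Mboat2 was the lowest suppressor, at 93.0 and 71.8 CPM. Of 26 iron handling genes, 17 were higher and 9 lower, with a median of 0.044 (0.0091 to 0.072) at percentile 95.7, which was 0.012 as a mean of per-cell CPM, 0.016 in cells assigned male, 0.072 with equal weights of the clusters, 0.080 with median-of-ratios scaling and 0.084 with scaling without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes. Among them, Trf, which encodes transferrin, stood at 36.7 and 51.0 CPM, and the metal transporter gene Slc39a8 at 53.8 and 38.1 CPM.

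Cell cycle genes were higher in the summed counts of cKO epithelial-like cells. All 38 measured E2F targets of replication and G1/S were higher, with a median log2 ratio of 0.32 (0.28 to 0.34) at percentile 100, from Slbp at 0.051 to Dut, which removes dUTP, at 0.54. All 36 measured genes of G2 and M phase were higher too, with a median of 0.30 (0.27 to 0.31) at percentile 100, with Bub1 at 0.43 and Ube2c at 0.39. No member of either list differed by 1.5-fold. Of 15 genes for E2F and pocket proteins, 13 were higher, with a median of 0.10 (0.065 to 0.15) at percentile 99.1, with Mybl2 at 0.49 and E2f3 at -0.20. This median was 0.044 with equal weights of the clusters, 0.064 as a mean of per-cell CPM, and 0.27 in cells assigned female and 0.049 in cells assigned male. Cluster 4, led by the mitotic genes Cenpf, Ccna2 and Plk1, held 13.5% of WT and 13.7% of cKO epithelial-like cells, but 20.5% and 26.4% of their UMIs, with medians of 39111 and 60079 UMIs per cell. With equal weights of the clusters the median of the G2 and M phase list was -0.020, and that of the E2F targets 0.15. Cluster 14, which that setting leaves out, had 892 CPM of the G2 and M phase list in WT and 1908 CPM in cKO, from 197 and 75 cells, and with equal weights of all 9 clusters the medians were 0.14 (0.098 to 0.18) and 0.17 (0.14 to 0.22). The E2F target median was 0.47 in cells assigned female and 0.18 in cells assigned male, which the libraries held in unequal parts.

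**Figure D2:**
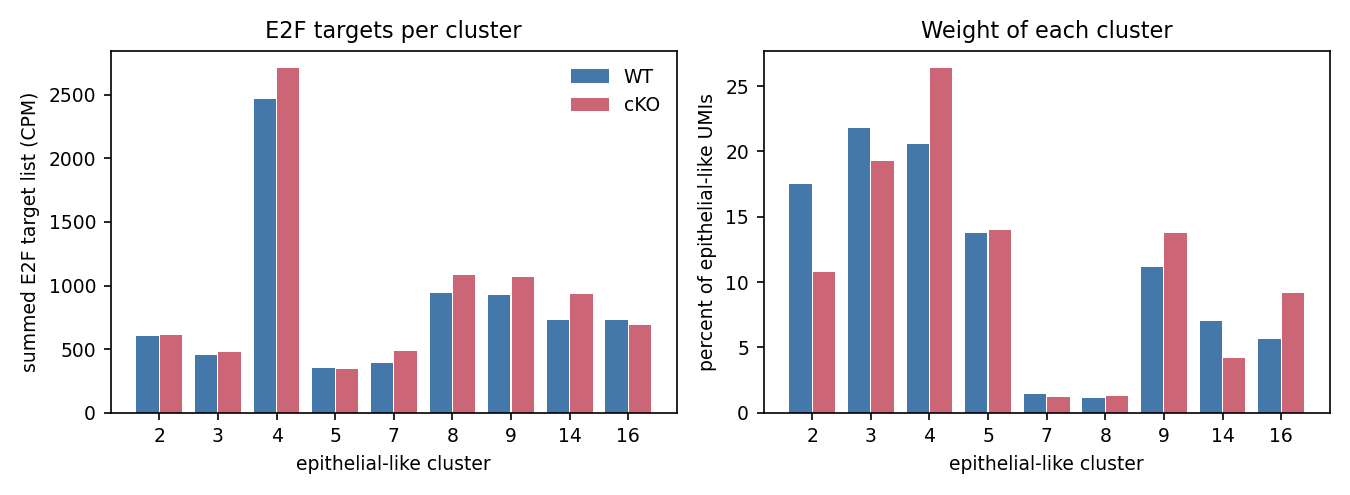
Summed level of the E2F target list in CPM (left) and percent of all epithelial-like UMIs (right) for each epithelial-like cluster (horizontal axes), in the WT and cKO libraries. Cluster 4 carries 2464 CPM in WT and 2708 CPM in cKO, and its share of UMIs is 20.5% and 26.4%.

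The planned call of cycling cells did not separate cycling from other cells. After thinning to 3000 UMIs, at least 2 UMIs of the G2 and M phase list were found in 50.9% of 2566 WT and 48.3% of 1486 cKO epithelial-like cells, a difference of -2.61 percentage points (-5.83 to 0.63), with 358 and 381 shallower cells left out. Without thinning the shares were 87.3% and 82.1%. Neutrophil-like cells, which are post-mitotic, met the same call in 59.0% and 47.2% of cells at medians of 3945 and 4733 UMIs, against 18867 and 24833 in epithelial-like cells, so the call is at background level and no order is read from it. At 10 UMIs, a call added after seeing the data, the epithelial-like shares were 10.7% (9.55 to 12.0) and 11.9% (10.3 to 13.7), with 1.60% and 0.92% in neutrophil-like cells.

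Interferon response and antigen presentation genes were lower in cKO epithelial-like cells. Of 37 measured genes of the interferon response and MHC class I, 35 were lower, 6 of them by at least 1.5-fold, with a median log2 ratio of -0.39 (-0.42 to -0.36) at percentile 0. The GTPase genes Gbp4 and Iigp1 stood at -1.22 and -1.21, H2-Q7 of MHC class I at -0.95 and Rsad2 at -0.79, while Cxcl9 was higher at 0.88. All 4 measured MHC class II genes were lower by at least 1.5-fold, with a median of -0.64 (-0.71 to -0.60) at percentile 0.010, and Cd74, the invariant chain, stood at 258 CPM in WT and 133 CPM in cKO. As a mean of per-cell CPM the class II median was -0.26. Of the 10 class II genes in the list only those 4 were measured. The guard against free RNA was not applied to lists, and class II genes and Cd74 are among the markers of dendritic-like cells. A part played by free RNA in the class II values was not tested. Of 29 inflammatory chemokine and NF-kB genes, 15 were higher and 14 lower, with a median of 0.017 (-0.041 to 0.034) at percentile 92.3, which had the other sign at -0.19 in cells assigned female, -0.11 in cells assigned male and -0.096 at Leiden resolution 0.5.

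Goblet cell genes were also lower, while mitochondrially encoded genes were higher. Of 17 measured goblet genes, 14 were lower, 7 by at least 1.5-fold, with a median of -0.49 (-0.52 to -0.46) at percentile 0. Ang4, an antimicrobial ribonuclease, stood at -1.86, Reg4 at -1.57 and Spink4 at -1.08, while Retnlb and Mptx1 were higher at 2.36 and 1.78. Cluster 14, led by the goblet-type genes Ang4, Spink4, Retnlb and Reg4 and as much by the Paneth-type genes Defa22, Defa3, Defa21, Defa24 and Lyz1, held 6.74% of WT and 4.02% of cKO epithelial-like cells, and with equal weights of the other clusters the goblet median was -0.18, and in cells assigned female -0.11. Of 13 mitochondrially encoded genes, 11 were higher, with a median of 0.23 (0.22 to 0.23) at percentile 100, with mt-Nd4 at 0.36 and mt-Nd6 at -0.11. This median was 0.13 at Leiden resolution 0.5 and 0.15 both as a mean of per-cell CPM and with equal weights of the clusters. Over all kept cells, the median mitochondrial share of UMIs, the measure used to filter barcodes, was 4.14% in WT and 4.86% in cKO. The higher levels therefore cannot be told apart from a difference in cell quality. Of 57 nuclear-encoded respiratory chain genes, 46 were higher, with a median of 0.072 (0.060 to 0.078) at percentile 99.99, which reversed to -0.033 with equal weights of the clusters. Of 34 genes of mitochondrial dynamics and the outer membrane, 19 were higher, with a median of 0.028 (0.0065 to 0.046) at percentile 98.2, which reversed to -0.010 with equal weights of the clusters and -0.030 as a mean of per-cell CPM, and Mtch2 was the 1 member that differed by 1.5-fold. Its paralog Mtch1 stood at 132 and 121 CPM.

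Sterol synthesis and Wnt target genes were lower. Of 32 genes of cholesterol and fatty acid synthesis, 30 were lower, with a median of -0.21 (-0.24 to -0.19) at percentile 0, and Hmgcs1 stood at -0.45 and Insig1 at -0.38. In cells assigned female this median was 0.031. Of 30 Wnt target and stem cell genes, 21 were lower, with a median of -0.18 (-0.19 to -0.16) at percentile 0, with Dkk2 at -0.67 and Apcdd1 at -0.56, and -0.015 with equal weights of the clusters. Cluster 2, with Lgr5 among its leading genes, held 21.5% of WT and 13.3% of cKO epithelial-like cells and 17.5% and 10.8% of their UMIs.

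The other epithelial lists had medians between -0.073 and 0.045. The median was -0.048 for 15 BCL2 family genes (percentile 31.9), 0.0086 for 25 genes of the integrated stress and unfolded protein responses (75.0), 0.045 for 24 NRF2 targets (96.1), -0.018 for 22 genes of fatty acid oxidation and PPAR targets (61.4) and -0.026 for 27 genes of glycolysis and hypoxia (44.1). It was -0.028 for 27 genes of colonocyte differentiation (46.6), among them Car4 at 1.74, Saa1 at 0.91 and Guca2b at -0.88. It was -0.061 for 29 regenerative or fetal-like genes (13.04), 0.025 for 24 p53 targets (89.3) and -0.073 for 31 genes of dissociation-induced stress (2.77), which was -0.27 in cells assigned female and 0.022 at Leiden resolution 0.5.

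**Figure D3:**
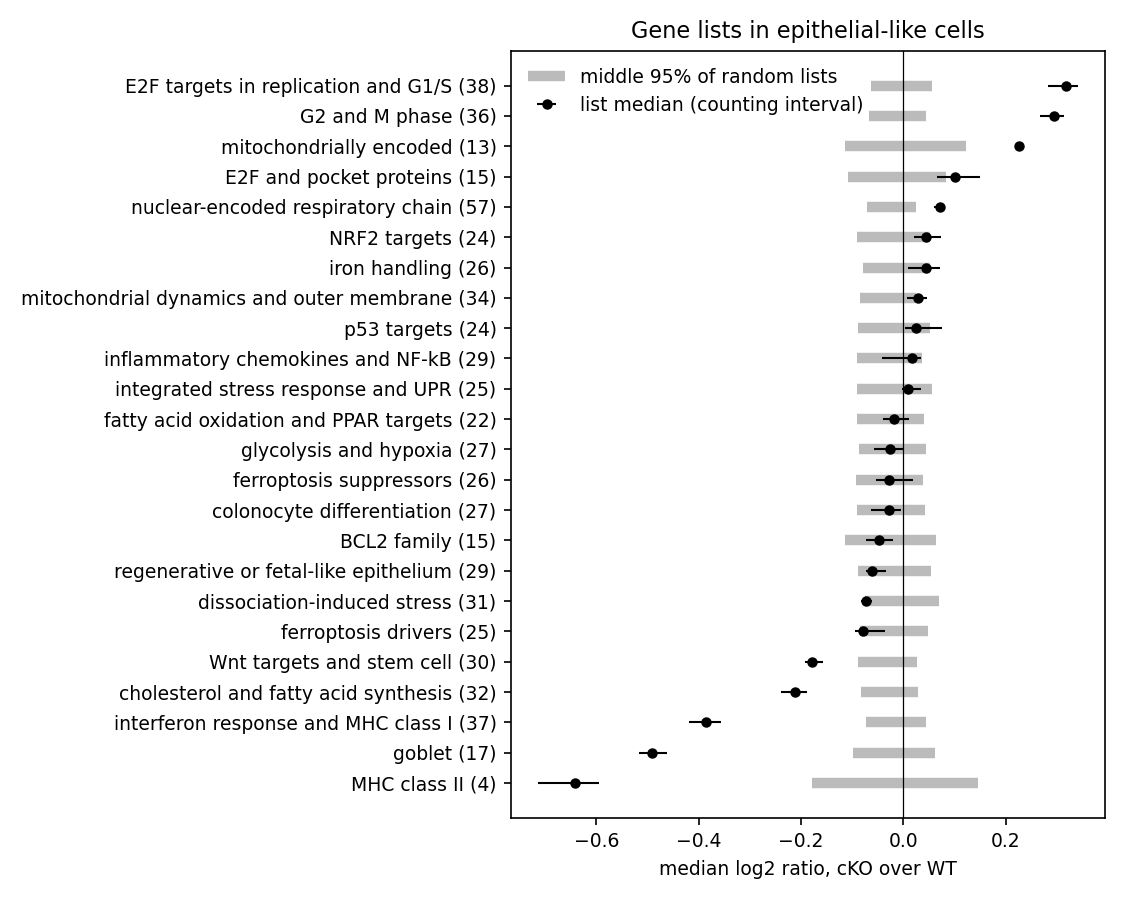
Median log2 ratio of cKO over WT (horizontal axis) for 24 gene lists in epithelial-like cells, with the number of measured genes in brackets, intervals for counting error and grey bars for the middle 95% of 10000 matched random lists. The E2F targets stand highest at 0.32 and MHC class II lowest at -0.64.

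By the rule for single genes, 267 genes were eligible in epithelial-like cells. The 15 largest ratios upward were led by Mptx2, a mucosal pentraxin, at 1.90 CPM in WT and 50.8 CPM in cKO, a log2 ratio of 4.74 (4.51 to 4.98). Onecut2, a homeobox transcription factor, followed at 42.9 and 102 CPM, 2.39-fold higher, then Stom at 0.73 and Gpx2, a glutathione peroxidase of the gut epithelium, at 887 and 1325 CPM, 0.58 (0.56 to 0.59). The others were Ggh, Gas5, Clu, Ppp2cb, Cadm1, Wdr89, Hnrnpa0, Lsm2, Peak1, Kcne3 and Cldn2, from 0.53 down to 0.37. Downward, Mtch2 and Ang4 were followed by the metallothionein gene Mt3 at 421 and 239 CPM, -0.82 (-0.84 to -0.79), Rnf32 at -0.79, Itln1 at -0.75, Fam89a at -0.64, Itpkc at -0.63, the chemokine gene Cxcl10 at -0.62, Spock2 at -0.60 and the Notch target Hes1 at 521 and 350 CPM, -0.57 (-0.60 to -0.55). Apcdd1, Mt4, Defa24, Map3k13 and Defa17 stood from -0.56 to -0.49. The defensin genes belong to a multigene family of near-identical copies, so their counts are uncertain. Rnf32 and Spock2 lead cluster 2, Peak1 cluster 8, and Ang4 and Defa24 cluster 14, while Mptx2 leads the unnamed cluster 13. That cluster, of 170 WT and 145 cKO cells, scored as epithelial-like but was left unnamed for a leading gene of another class. It did not enter the guard against free RNA, so for Mptx2 free RNA from cluster 13 was not guarded against. The guard compares classes, so for Ang4 and Defa24 free RNA from cluster 14 within the class was not guarded against either. With 75 cKO cells, cluster 14 was not among the 8 clusters checked for direction.

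B-like cells made up a larger share of the named cells outside the epithelial-like class in the cKO library, and mast, fibroblast and plasma-like cells a smaller share. Of 1296 WT and 1786 cKO named cells outside the epithelial-like class, B-like cells were 3.63% (2.68 to 4.79) and 18.0% (16.2 to 19.8). The cKO base includes 48 squamous-like cells (2.69%), which are epithelial. Neutrophil-like cells were 16.98% (14.97 to 19.1) and 21.6% (19.7 to 23.6). Mast and basophil-like cells were 10.4% (8.81 to 12.2) and 2.91% (2.18 to 3.80), fibroblast-like cells 12.7% (10.96 to 14.7) and 4.65% (3.72 to 5.73), and plasma-like cells 3.55% (2.61 to 4.71) and 1.23% (0.77 to 1.86). The intervals overlapped for T-like (22.2% in both), macrophage and monocyte-like (20.8% and 18.5%), dendritic-like (4.09% and 3.98%), endothelial-like (4.48% and 3.25%) and erythroid-like cells (1.08% and 0.95%). Of all kept cells the picture differed, since fewer cKO cells were in unnamed clusters. T-like cells were 3.98% and 9.05%, macrophage and monocyte-like cells 3.73% and 7.54%, neutrophil-like cells 3.04% and 8.80% and B-like cells 0.65% and 7.32%, while the intervals of the difference included 0 for fibroblast-like (-0.39, -0.92 to 0.17) and plasma-like cells (-0.13, -0.42 to 0.17). With all deposited barcodes the differences were smaller, at 0.72 percentage points for T-like cells, of which a cluster was then left unnamed, 2.55 for macrophage and monocyte-like, 3.597 for neutrophil-like and 4.43 for B-like cells. Epithelial-like cells were 40.4% (39.2 to 41.5) of all kept WT cells and 42.5% (41.1 to 44.0) of cKO cells, a difference of 2.18 percentage points (0.32 to 4.04), which was -18.2 among named clusters and -13.2 with all deposited barcodes. Tumours of each genotype were pooled before dissociation, and unnamed clusters held 41.7% of WT and 16.8% of cKO cells, so shares describe these 2 suspensions.

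**Figure D4:**
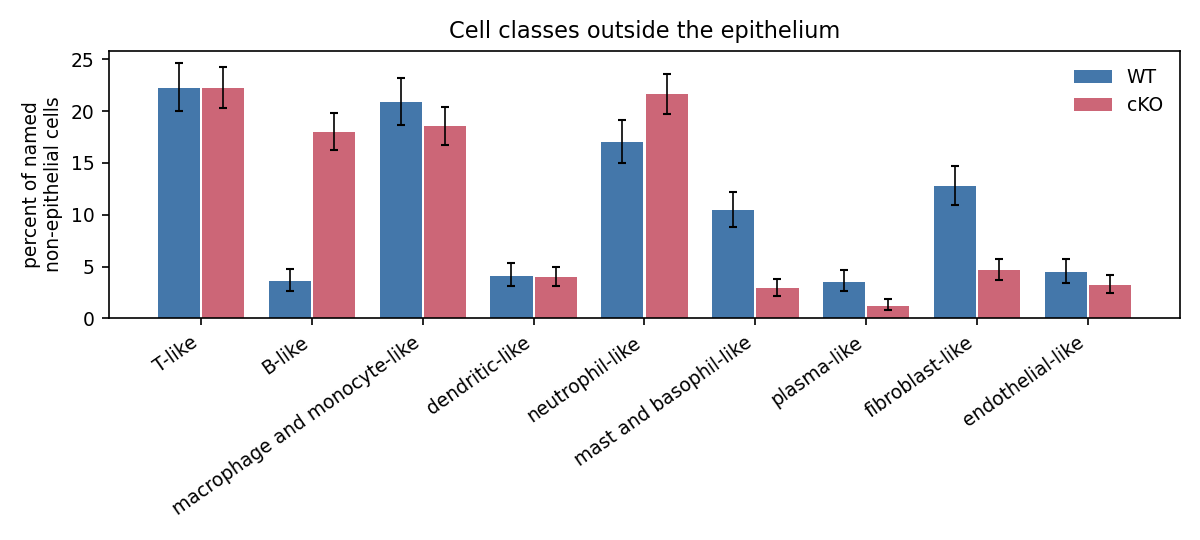
Percent of named cells outside the epithelial-like class (vertical axis) in 9 cell classes of the WT and cKO libraries, with exact 95% binomial intervals that cover counting error only. The base includes 48 squamous-like cells in cKO. B-like cells stand at 3.63% in WT and 18.0% in cKO, and fibroblast-like cells at 12.7% and 4.65%.

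Macrophage and monocyte-like cells (270 WT, 331 cKO) had higher levels of inflammatory genes in the cKO library. Of 25 measured inflammatory genes, 22 were higher, 13 of them by at least 1.5-fold, with a median log2 ratio of 0.71 (0.65 to 0.77) at percentile 100. Il6 stood at 12.1 CPM in WT and 139 CPM in cKO, 3.50 (3.06 to 4.001), Nos2, the inducible nitric oxide synthase gene, at 8.10 and 103 CPM, 3.65 (3.12 to 4.28), and Tnf at 278 and 697 CPM, 1.33 (1.22 to 1.43). Of 26 alternative and tissue macrophage genes, 18 were lower and 9 of these by at least 1.5-fold, with a median of -0.36 (-0.45 to -0.29) at percentile 0 and of -0.063 with equal weights of the clusters. The libraries held the macrophage types in different parts. At Leiden resolution 2, the cluster led by Ccl24, Chil3 and Inhba held 66 WT and 139 cKO cells, with an inflammatory median of 0.75 (0.69 to 0.81), and the deeper of the 2 clusters with C1qa and C1qc among their leading genes held 91 and 82, with 0.27 (0.20 to 0.42). In the shallow cluster, of 114 and 110 cells, it was -0.22 (-0.52 to 0.30). The tissue macrophage medians of these clusters were -0.41, -0.27 and 0.19. In the class as a whole, Mgl2 stood at -1.05 and Selenop at -0.77, but Il10 at 2.36 and Arg1, arginase, at 1.12. Among 783 eligible genes, the rule named Csf3 (3.96), Saa3 (3.67), Il6, Hp (3.21) and Ang4 (2.89) upward, and Gsdmc2 (-3.44), H2-M2 (-1.52), Jmy (-1.46), Bzw2 (-1.31) and Lpl (-1.24) downward. Most of these genes had their highest level in another class, in the library where they were higher. It lay in fibroblast-like cells for Csf3, Saa3, Il6 and Lpl, in neutrophil-like cells for Hp and in epithelial-like cells for Gsdmc2. For Jmy it lay in B-like and for Bzw2 in mast and basophil-like cells, and for Ang4 and H2-M2 in macrophage and monocyte-like cells. Epithelial RNA was present in both libraries, with Epcam at 252 CPM in WT and 118 CPM in cKO macrophage and monocyte-like cells.

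T-like cells (288 WT, 397 cKO) had lower levels of regulatory and T helper 17 genes and higher levels of naive and memory genes in the cKO library. Of 20 regulatory T cell genes, 17 were lower, with a median of -0.34 (-0.42 to -0.26) at percentile 0, with Foxp3 at 156 and 97.2 CPM, -0.69 (-0.90 to -0.47). Foxp3 also leads cluster 15, which held 122 of the WT and 139 of the cKO T-like cells, while cluster 12, led by Xcl1, held 117 and 207, and cluster 23, led by Trdc, Cd163l1 and Il17a, 49 and 51. With equal weights of clusters 12 and 15 the regulatory median was -0.23. With all deposited barcodes it was -0.066, but there the class held the cluster with Foxp3 among its leading genes alone (144 and 151 cells). The other T cell cluster (183 and 266 cells) was left unnamed. Its leading genes held 4 markers of natural killer and innate lymphoid cells and 2 of T cells. In the main setting cluster 12 held 2 of each, so the T-like class may include such cells, and its cytotoxicity and type 3 values may reflect them. Of 16 T helper 17 and type 3 genes, 13 were lower, with a median of -0.28 (-0.34 to -0.22) at percentile 0. Over the main setting and 12 alternatives this median ran from -0.32 to -0.18. Il22 stood at -1.12, while Il17f was higher at 1.88. Of 15 naive and memory genes, 11 were higher, with a median of 0.29 (0.19 to 0.35) at percentile 100, with Lef1 at 0.54. Foxp1, Bach2, Satb1 and Klf2, which were among the higher members, had their highest level in B-like cells (Foxp1 at 3474 CPM), whose share differed between the libraries, while Lef1 and Tcf7 (0.49) had it in T-like cells. The medians were 0.066 (-0.0049 to 0.23, percentile 89.3) for 24 cytotoxicity genes, with Eomes at 2.12 and Ifng at -0.96, and -0.27 with all deposited barcodes, -0.14 at Leiden resolution 2 and -0.13 with equal weights of clusters 12 and 15, and 0.019 (-0.10 to 0.085, percentile 63.6) for 19 exhaustion and checkpoint genes. Among 800 eligible genes, the rule named Zmat4 (1.49), Gzma (1.46), Hdac9 (1.46), Fgf13 (1.34) and Slc15a2 (1.15) upward, and the chemokine and cytokine genes Ccl20 (-4.43), Ccl1 (-2.42), Csf2 (-2.10) and Cxcl10 (-1.43) and the histone gene Hist1h1b (-1.24) downward. Histone transcripts mostly lack poly(A) tails.

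Neutrophil-like cells (220 WT, 386 cKO) had higher levels of most measured activation and maturation genes in the cKO library. Of 31 measured genes of neutrophil activation and maturation, 25 were higher and 12 of these by at least 1.5-fold, with a median of 0.26 (0.21 to 0.36) at percentile 100. The class pools cluster 6, led by Retnlg and S100a8, with 158 WT and 305 cKO cells, and cluster 21, with 62 and 81. The median was 0.34 in cluster 6, 0.39 with median-of-ratios scaling and 0.42 with all deposited barcodes. The granule protein genes Camp and Ngp stood at 2.55 (1.60 to 3.88) and 2.04 (1.73 to 2.38), Mmp8 at 1.53 and Retnlg at 1.42, while the granule protease gene Mmp9 stood at 0.11 (-0.056 to 0.27) and Cd274 was lower at -0.41. The cytokine and chemokine genes Ccl3, Tnf, Cxcl3, Il1b, Cxcl2 and Ccl4 differed less, from 0.087 for Ccl3 to 0.36 for Ccl4. Ptgs2 and Icam1 stood at -0.052 and -0.083, so the class is not read as more activated. Cxcr2 stood at 0.094 (-0.074 to 0.27) and Cxcr4 at -0.33 (-0.54 to -0.12), unlike the granule genes Camp and Ngp. The class is therefore not read as more mature either. Over all 7352 measured genes of this class the median was -0.28. Cstdc5, of a stefin gene cluster with similar copies, had no UMI in WT and 272 in cKO. This was 43.7-fold higher against a floor of 3 counts in WT, and the exact interval of the log2 ratio reached down to 5.14. Among 984 eligible genes, the rule also named P2rx7 (3.18), Chil3 (2.75) and Gab3 (2.66) upward, and Gkap1 (115 UMIs in WT and 1 in cKO, -7.32, interval -13.2 to -5.39), Mt3 (-2.32), Cipc (-2.27), Defa22 (-2.17) and Mt4 (-1.89) downward. Mt3, Mt4 and Defa22 had their highest level in epithelial-like cells, and Epcam stood at 373 CPM in WT and 242 CPM in cKO neutrophil-like cells. Their direction rests on 1 cluster with at least 100 cells in each library.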

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

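No test of an explanation was run for the clusters described here, and the rule that named clusters or left them unnamed was set after the clusters were seen. Each cluster was set apart because 1 library held cells and the other held none.

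Squamous-like cells, led by the basal keratin gene Krt5, Lgals7, Krtdap and Trp63, were 48 of 4388 kept cKO cells, 1.09% (0.81 to 1.45), at a median of 34810 UMIs. None was found among 7243 WT cells, which allows a share of up to 0.0414% (3 counts). A stratified squamous epithelium with these genes lines the anal canal. With 1 library per genotype, the presence of such a cluster describes the tissue that entered that suspension.

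Among the clusters left unnamed for carrying markers of several classes, 3 were found in WT and not in cKO, where 0 of 4388 cells allows up to 0.0684% by the same limit. Cluster 28, with Ccl8 among its leading genes, held 46 cells or 0.64% of kept WT cells, cluster 29, led by Cxcl13 and Cxcl12, 42 cells or 0.58%, and cluster 31, led by Mybpc1, 36 cells or 0.50%. With all deposited barcodes, the cluster led by Cxcl13 and Cxcl12 held 44 WT cells and 1 cKO cell. Those led by Ccl8 and by Mybpc1 held 46 and 35 WT cells and 0 cKO cells.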

How the results depend on the processing

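The settings for sex of origin, cluster 13, the cells of at least 5000 UMIs, clusters 1 and 13 together, named clusters only, the 10 UMI call and the single thinning draw were chosen after seeing the data, and the others before. With 1 library per genotype leaving out a library was not possible. No paired analysis was possible because each genotype has 1 library and no test was made. Depth limits the smaller classes: 86% of simulated 1.5-fold changes were recovered in neutrophil-like cells. For the results fixed in advance, 91 values kept within their counting interval or, for the 14 counts of named genes, within 1.5 times the count, 27 moved beyond it and 4 reversed, and for the other lists and shares 295, 161 and 18. The cause was not tested, except that the weighting settings show the part played by unequal clusters.

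Mtch2 stayed lower in all 14 alternatives, and moved to -2.08 at Leiden resolution 0.5, -1.64 as a mean of per-cell CPM, -1.85 with equal weights of clusters, -1.51 in cells assigned female and -2.18 in cells assigned male. Tfrc moved to 0.070 with all deposited barcodes, 0.0016 as a mean of per-cell CPM, 0.013 with equal weights, 0.085 with cluster 13 and 0.48 in female cells. E2f4 reversed to -0.058 as a mean of per-cell CPM and moved to 0.30 in female cells. Ferroptosis drivers moved to -0.01 with all barcodes, and to -0.033 both with equal weights and with cluster 13. Suppressors moved to -0.075 at resolution 0.5 and -0.076 with equal weights. E2F targets stayed higher in all 16 alternatives. They moved to 0.26 with all barcodes, 0.24 at resolution 0.5, 0.36 with a mitochondrial maximum of 10%, 0.38 without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, 0.35 with median-of-ratios scaling, 0.22 per cell, 0.15 with equal weights, 0.47 in female cells and 0.18 in male cells.

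The epithelial-like share difference moved to 5.05 percentage points at resolution 0.5 and reversed to -13.2 with all barcodes, -19.7 with clusters 1 and 13 and -18.2 among named clusters. The cycling share difference moved to 1.19 at 10 UMIs. A single random draw gave -3.88 in place of -2.61. The 30 named epithelial genes kept their direction in every alternative except in cells assigned female (26) and male (29), in part because the rule itself asked for 1 direction across clusters.

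A reversal was counted where the counting interval excluded 0. As a mean of per-cell CPM, the reversed medians were -0.026 for G2 and M phase, -0.074 for the nuclear-encoded respiratory chain, -0.030 for mitochondrial dynamics, 0.011 for the BCL2 family and 0.038 for colonocyte differentiation. With equal weights they were -0.020, -0.033, -0.010 and 0.0069 for the first 4 of these lists, in that order. In female cells they were 0.064 for the BCL2 family, 0.031 for cholesterol and fatty acid synthesis, 0.080 for colonocyte differentiation and 0.13 for the fetal-like list, and in male cells -0.041 for p53 targets. Colonocyte differentiation also reversed under the scaling without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes (0.014) and median-of-ratios scaling (0.007). At resolution 0.5 NRF2 targets reversed to -0.0069 and dissociation-induced stress to 0.022. Lists whose interval included 0 changed sign as well, beyond that interval: the stress responses to -0.11 in female cells and -0.028 with members of at least 1 CPM, fatty acid oxidation to between 0.0176 and 0.0249 in 3 settings, glycolysis and hypoxia to 0.082 in male cells and 0.013 and 0.009 in the 2 scalings, chemokines and NF-kB to between -0.073 and -0.19 in 6 settings, and T cell cytotoxicity to between -0.13 and -0.27 in 3.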

Other observations

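Of the tests below, those of cluster weights, of the cycling share at 10 UMIs, of Mtch2 against cell depth, of neutrophil S100a8 and S100a9 and of macrophage clusters at Leiden resolution 2 were chosen only after the results were seen.

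The mix of male and female cells differed between the libraries. From Xist and Y-linked transcripts, 981 WT epithelial-like cells were assigned female and 965 male, against 339 and 872 in cKO, and the rest had too few such transcripts or a mix. T-like cells were 107 female and 93 male in WT and 43 and 240 in cKO. The libraries thus pool mice of both sexes in unequal parts, which the labels do not record. The goblet gene medians were -0.11 in female and -0.64 in male cells, while those of interferon response and MHC class I genes were -0.43 and -0.36. No intervals were computed for these medians, and the difference between the sexes was not tested.

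Cell cycle genes were higher in the summed counts of cKO epithelial-like cells. A candidate explanation is the larger weight of the cycling cluster 4, whose cells were deeper in cKO. With the WT shares of UMIs given to all 9 clusters in both libraries, the G2 and M phase median was 0.0615 (0.031 to 0.080), so unequal shares may account for most of that list. Without cluster 14, whose own median was 1.34 at 75 cKO cells, it was -0.029 (-0.056 to -0.0051). The same shares leave part of the E2F target list unexplained, whose median was 0.143 (0.10 to 0.16), above the 0.052 that bounds the middle 95% of random lists, with 29 of 36 measured members higher, and 0.10 (0.077 to 0.13) without cluster 14. Whether more epithelial cells cycled with the cKO genotype cannot be told apart from counting error, since the difference at 10 UMIs was 1.19 percentage points (-0.85 to 3.305).

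Mtch2 transcripts remained in cKO epithelial-like cells at 23.8 CPM. If a minority of cells had kept the WT level and the rest had no Mtch2 transcript, 79.8% of cells thinned to 20000 UMIs would lack a Mtch2 UMI. If all shared 1 level, 63.8% would lack it. The observed 62.5% (59.4 to 65.5) argues against such a minority among otherwise empty cells, for the cells covered. These were the 1442 WT and 997 cKO epithelial-like cells with at least 20000 UMIs. Shallower cells were not examined, among them most cells of clusters 7 and 8, with cKO medians of 2252 and 3272 UMIs. The observed share cannot tell whether a minority stood beside cells that kept a lower level. Free RNA at a like amount per droplet would dilute with depth. Mtch2 stood at 23.1 CPM in 852 cKO cells of at least 30000 UMIs and 24.97 CPM in 704 under 10000, a ratio of 0.93 (0.72 to 1.21). This cannot decide the question, because depth goes with the cluster and the ratio has no WT reference. In WT the shallow clusters 7 and 8 stood at 42.1 and 47.1 CPM, against 81.7 to 115 CPM in the deep clusters 3, 4, 9 and 16. Clusters 7 and 8 kept 0.55 and 0.48 of the WT level in cKO, against 0.19 to 0.30 in those deep clusters. A planned estimate with neutrophil markers put free RNA at 11.9 of the 23.8 CPM from the planned pool of shallow barcodes, and at 24.03 CPM or 101% from cluster 1, a pool not planned, but it was void, because Pglyrp1 gave 50.7% of the marker signal and was higher in epithelial-like (1080 CPM) than in neutrophil-like cells (798 CPM). Free RNA stays open, both at a like amount per droplet and scaling with a cell's own yield. So do transcripts that lost a floxed exon but keep their 3' end.

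Inflammatory genes were higher in cKO macrophage and monocyte-like cells. Within the larger of the 2 clusters the median was 0.69 (0.62 to 0.74), so the pattern does not need a different mix of the 2. The class sums rest mostly on that cluster, whose cells had medians of 19022 UMIs in WT and 16313 in cKO, against 1361 and 1531 in the other. Its median was therefore bound to lie near that of the class. At Leiden resolution 2 the larger cluster parts into one led by Ccl24 and Chil3, with 66 WT and 139 cKO cells, and one led by C1qc and C1qa, with 91 and 82. With equal weights of the 3 clusters at that resolution the median was 0.6439 (0.55 to 0.69), which argues against this mix as the whole cause, but it was 0.75 in the first and 0.27 in the second, so the pattern rests mostly on the first, and a mix of cell states within it stays open. Free RNA from neutrophil-like cells was argued against by S100a8, at 147 CPM in macrophage-like and 40442 CPM in neutrophil-like cells of the cKO library. It allows 0.36% of neutrophil RNA, which would give the 25 measured members a median of 0.0033. A planned test on 16 members at least as high in macrophage-like cells was void, since they were picked by their level in the cKO library. A difference between tumours, sites or sexes within the pools was not tested and, like the genotype, may account for the pattern.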
